A study of Ovis aries with 27 samples.

How the data were processed

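RNA from the heart septum of 27 sheep fetuses was measured on 1-colour Agilent arrays, 1 array per fetus, with cRNA labelled with Cy3, per the labels. The ewes received a continuous infusion of cortisol at 1 mg/kg/d or of vehicle. There were 4 groups: control at 130 d of gestation (n = 6), cortisol at 130 d (n = 6), control at 140 d (n = 8) and cortisol at 140 d (n = 7). The younger groups were sampled between 129 and 131 d, and the older groups between 139 and 144 d. The labels give an infusion of about 10 d from about 120 d of gestation for the younger cohort and from about 115 d for the older cohort, about 25 d in all. Another of the labels gives a start at about 115 d for all ewes, which would make the infusion of the younger cohort longer. The 2 ages were separate cohorts of ewes with infusions of different length, so age, cohort and length of infusion cannot be told apart in any comparison of 140 d with 130 d. The 8 older controls came from 7 ewes, and the labels do not say which 2 were twins, so each fetus was treated as independent.

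The deposited scanner files hold spot intensity values that were background-subtracted and detrended but not normalized between arrays, per the file headers, and were made with Agilent Feature Extraction 10.1.1.1, per the submitters' processing notes. A table of processed values that the authors deposited holds log2 values. Set against the scanner values of the same arrays, each column was log2 of the processed intensity minus 1 constant per array (largest residual SD 2e-06 on the log2 scale), with column medians between 0.09 and 0.12. What that constant was computed from is not stated. The authors' flags for spots well above background, saturated spots and outlying spots were also used, per the file headers. No spot was saturated on any array (0 spots).

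The arrays carried 15008 probes besides control spots on 15208 spots, since 50 probes were spotted 5 times. Values were log2 of the processed intensity minus the array's 75th percentile of it. Outlying spots were left out and spots of one probe were averaged. The 12778 probes that were well above background on at least 6 arrays were tested, and 83 of them had a missing value on some array. Symbols came from the files' own names, from gene identifiers or from the supplied sheep reference table of RefSeq accessions. In this way 1142 of the tested probes (8.94%) were named, for 757 genes. Most of the other 11636 tested probes are expressed sequence tags with no symbol in the tables used, so a count of probes is not a count of named genes. A gene with several tested probes was represented by the probe with the highest mean over all arrays. Of 355 genes with several tested probes, 53 had all probes past the threshold in the same direction in the control age comparison, 45 had some past and some not, and 0 had opposite calls.

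Group means were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with all 4 groups in a single fit and no batch term. Probes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 12778 probes. The comparisons were cortisol against control at each age, 140 d against 130 d within each arm, and the difference of the cortisol effect between the ages. Changes are log2 differences with their standard errors (SE), and p values are 2-sided.

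Before the data were examined, 24 gene lists were fixed, and 15 of them had the minimum of 5 measured genes under the symbols used. They cover corticosteroid, renin-angiotensin and insulin-like growth factor genes, cell cycle, oxidative phosphorylation, fatty acid oxidation, glycolysis and glucose transport, calcium handling and ion channels, extracellular matrix, apoptosis, ribosomal proteins, proteasome, interferon response with antigen presentation, and markers of endothelial cells, fibroblasts, immune cells and adipocytes. They were tested with limma's camera at a preset inter-gene correlation of 0.01 against the other named genes and adjusted over the 15 lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were alternatives. Missing values were filled with the group mean for the list tests only. The other 9 lists had fewer genes under the symbols used and were not tested, and their members are given as counts. The glucocorticoid-responsive list was among them, since its member TXNIP was on the array under an older symbol, VDUP1, and was not counted. Exact permutation tests of list means per array were added after the data were seen.

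Genes named in the text followed a rule fixed in advance. It took, per direction, the 6 genes with the largest change past the threshold, or those with the smallest p where fewer passed. It added 3 members of each list past its test, and NR3C1, HSD11B1 and HSD11B2 in every comparison. For the difference between the ages it took 3 genes per direction. FKBP5, PER1, TSC22D3 and NR3C2, which the rule also asked for, had no named probe among those tested. The rule named 1 gene that is not reported here. In the comparison of ages within the cortisol arm the rule named list members and the last 3 genes only.

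The procedure was tested on simulated data in which 67, 67 and 66 of the 12778 probes were changed by 3 sizes. For cortisol at 130 d it recovered 29.9% of 67 probes changed 1.5-fold, 73.1% of 67 changed 2-fold and 95.5% of 66 changed 4-fold, with 7 false calls. For cortisol at 140 d the recovery was 44.8%, 76.1% and 98.5% with 10 false calls, and for age in the controls 41.8%, 71.6% and 95.5% with 6 false calls. In a simulated comparison of 21 lists, the 1 shifted list was called and 0 of the others. The simulated values were drawn independently for each probe. The false calls and the list result therefore do not show how the tests behave where genes vary together. The number of arrays limits the precision of each value.

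The arrays lay on 5 slides, each scanned on its own, so slide and scan are the same batch. Slides 2, 3 and 4 held all 4 groups, slide 5 held 140 d arrays of both arms, and slide 1 held 1 array. Slides 2 and 3 had 2 arrays of each group. Slide 4 had 2 of each 130 d group but 1 of each 140 d group. Slide 5 had 3 control arrays and 1 cortisol array. Alternatives were quantile normalization, a median shift, normexp background correction with an offset of 50, the authors' table, no filter and a stricter filter on dim probes, slide as a fixed or random block, the replicate number as a block, the compared groups alone, eBayes with trend and robust settings, array weights, the mean of a gene's probes, an adjusted p under 0.10, and leaving out each array in turn. Each of slides 2, 3 and 4 alone, and the fit without the 2 arrays that stood apart, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.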

Results

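Transcript levels were measured in the heart septum, the muscular wall between the ventricles, of 27 fetal sheep in the last part of gestation. Their mothers had received cortisol, the main glucocorticoid of sheep, or vehicle. The design asks what a raised maternal cortisol level does to gene expression in the fetal heart at 130 d and near term, and how expression changes between those ages. There were 6 control and 6 cortisol fetuses at 130 d, and 8 control and 7 cortisol fetuses at 140 d. Between 77.0% and 87.0% of the spots were well above background on each array. Arrays of the younger fetuses were brighter, with 75th percentiles of intensity of 1160 ± 101 (SD, n = 6) in controls and 1093 ± 77.0 (SD, n = 6) with cortisol. Those at 140 d were 838 ± 59.3 (SD, n = 8) and 884 ± 149 (SD, n = 7). Each array was scaled to its own 75th percentile. The first principal component held 23.2% of the variance and the second 12.1%.

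**Figure D1:**
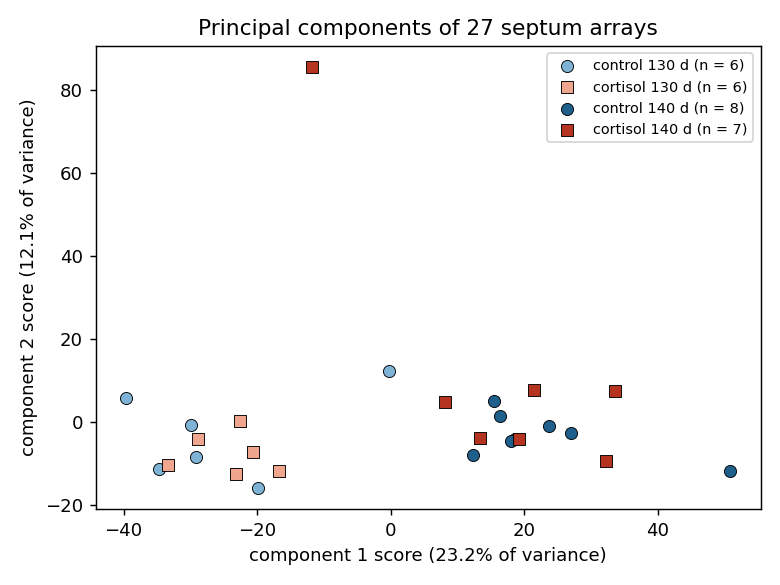
Scores of the 27 arrays on the first 2 principal components of the tested probes, with the share of variance on each axis (23.2% and 12.1%). Each point is 1 fetus, and colour and shape give the group. All control arrays at 140 d scored 12.4 or more on the first component, the 130 d arrays scored -0.298 or less, cortisol arrays at 140 d went down to -11.7, and cortisol 140 d replicate 4 stands apart at 85.6 on the second.

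Between 130 d and 140 d in control fetuses, 4 of 10 measured cell cycle genes and 6 of 7 interferon genes fell, and 4 of 6 genes of oxidative phosphorylation and 5 of 10 of glycolysis rose (8 against 6 arrays). These lists passed camera at its preset correlation, and 0 of 15 lists passed with an estimated correlation. With fry 9 of 15 passed, these lists among them. The mitochondrial nucleotide carrier SLC25A33 rose by 1.26 ± 0.20 on the log2 scale (SE, adjusted p = 0.000252, higher than the 130 d mean in 8 of 8 fetuses). Thymidylate synthase, TYMS, which makes a DNA precursor, fell by 1.49 ± 0.38 (SE, adjusted p = 0.00759). The interferon-induced chemokine CXCL10 fell by 4.49 ± 0.91 (SE, adjusted p = 0.00159). HSD11B1, the enzyme that regenerates active glucocorticoid from its inactive form, rose by 0.95 ± 0.25 (SE, adjusted p = 0.0105, 8 of 8 fetuses). In all, 2443 of 12778 probes passed limma's test, 1248 higher and 1195 lower at 140 d, and among the 757 named genes 85 rose and 72 fell. The 2 ages were separate cohorts. The count was 536 with normexp background correction, and the share of higher probes, 51.1% here, was 70.6% with a median shift.

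The other named genes with the largest rises were ITGB6, an integrin subunit (1.89 ± 0.54), TUBA4A, an alpha-tubulin (1.82 ± 0.38), ALDH1A1, which makes retinoic acid (1.53 ± 0.37), UGT1A9, a glucuronosyltransferase (1.35 ± 0.47), and MLN, the gut peptide motilin (1.14 ± 0.24), each with its SE and adjusted p values between 0.00214 and 0.0448. UGT1A9 lost its call in 8 of 14 fits with 1 array left out. The other largest falls were in AHSP, the chaperone of alpha-hemoglobin (-3.26 ± 0.70), ISG15, an interferon-induced ubiquitin-like protein (-3.01 ± 0.58), CATHL1B, an antimicrobial cathelicidin (-2.55 ± 0.74), MX1, an antiviral GTPase (-2.06 ± 0.46), and INHBA, the subunit of activin A (-2.0 ± 0.51). AHSP was well above background on 4 of the 8 arrays at 140 d and CXCL10 on 6 of 8, against 6 of 6 for both at 130 d, so these falls are not exact folds. AHSP was -0.999 with normexp background correction (adjusted p = 0.125) and CXCL10 -2.79. The glucocorticoid receptor gene NR3C1 differed by 0.20 ± 0.16 (SE, adjusted p = 0.422) and HSD11B2, which inactivates cortisol, by 1.44 ± 0.56 (SE, adjusted p = 0.0712), and neither passed. HSD11B2 was 0.87 without control 140 d replicate 3 and passed at 1.71 without control 140 d replicate 6 (adjusted p = 0.0333), at 1.55 with quantile normalization (adjusted p = 0.0469) and at 1.53 with a median shift (adjusted p = 0.0484). With normexp, 18 of the 31 named genes past the threshold did not pass, among them HSD11B1 (0.87), TYMS (-0.90), AURKA (-0.29), TGFB1 (-0.32), TGFB2 (-0.65) and LYZ (-0.57).

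Of 10 measured cell cycle genes, 4 fell and 6 did not pass over all probes, and 7 fell when adjusted over the list alone. CDK4, a kinase of the G1 phase, fell by 0.26 ± 0.08 and AURKA, a mitotic kinase, by 0.75 ± 0.24 (SE). With 1 array left out, AURKA lost its call in 5 of 14 fits and CDK4 in 1 of 14. Over all 29 alternatives AURKA lost its call in 9 and CDK4, as weak as -0.17, in 4. The list had a mean log2 change of -0.67 (camera adjusted p = 0.0214; adjusted p = 0.347 with an estimated correlation). Of 6 genes of oxidative phosphorylation, 4 rose over all probes and 6 adjusted over the list alone. The ATP synthase subunits ATP5PD and ATP5MC1 rose by 0.71 ± 0.11 and 0.69 ± 0.15, and the complex I subunit NDUFA12 by 0.69 ± 0.15 (SE). That list's mean change was 0.55 (camera adjusted p = 0.000493; adjusted p = 0.196 with an estimated correlation). Over the alternatives ATP5MC1 went down to 0.34, and it lost its call in 1 of them (adjusted p = 0.0937 with limma). Of 10 genes of glycolysis and glucose transport, 5 rose and 5 did not pass, and 6 rose adjusted over the list alone. They included GAPDH (0.59 ± 0.15), ALDOA (0.52 ± 0.12) and HK1 (0.47 ± 0.13), enzymes of glycolysis, with a list mean of 0.36 (camera adjusted p = 0.0214; adjusted p = 0.196 with an estimated correlation).

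Of 7 genes of the interferon response and antigen presentation, 6 fell over all probes and 7 adjusted over the list alone, with a mean of -2.02 (camera adjusted p = 8.87e-05; adjusted p = 0.196 with an estimated correlation). Without control 130 d replicate 3 the interferon mean was -1.55 and CXCL10 was -3.73. The immune cell markers were lower beside the interferon genes. Of 8 measured, 3 fell over all probes and 3 adjusted over the list alone: ITGB2, a leukocyte integrin (-1.02 ± 0.24), FCER1G, a receptor chain of myeloid cells (-1.16 ± 0.31), and LYZ, lysozyme (-1.41 ± 0.41). Their mean was -0.77 (camera adjusted p = 0.0159; adjusted p = 0.196 with an estimated correlation). Of 16 extracellular matrix genes, 3 fell over all probes and 2 adjusted over the list alone, among them the growth factors TGFB2 (-0.98 ± 0.25) and TGFB1 (-0.74 ± 0.21) and the collagen COL3A1 (-0.59 ± 0.21), with a list mean of -0.30 (camera adjusted p = 0.0341; adjusted p = 0.494 with an estimated correlation). All 5 fibroblast markers were negative beside them, with a mean of -0.43 (camera adjusted p = 0.0625; adjusted p = 0.0455 with fry). Except for VIM these markers (COL1A2, COL3A1, DCN and FBLN1) are also in the matrix list, so they are not separate evidence. With 1 array left out, COL3A1 lost its call in 11 of 14 fits and the matrix list in 4 of 14. Of 8 adipocyte markers, 3 rose over all probes and 3 adjusted over the list alone: LPL, lipoprotein lipase (0.77 ± 0.18), LEP, leptin (0.51 ± 0.11), and PLIN1, a lipid droplet protein (0.48 ± 0.12). Their mean was 0.46 (camera adjusted p = 0.0214; adjusted p = 0.238 with an estimated correlation). LPL is also a member of the fatty acid oxidation list, and a further LEP probe had the opposite sign without a call, so that with the mean of its probes LEP was 0.21 and did not pass (adjusted p = 0.219).

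**Figure D2:**
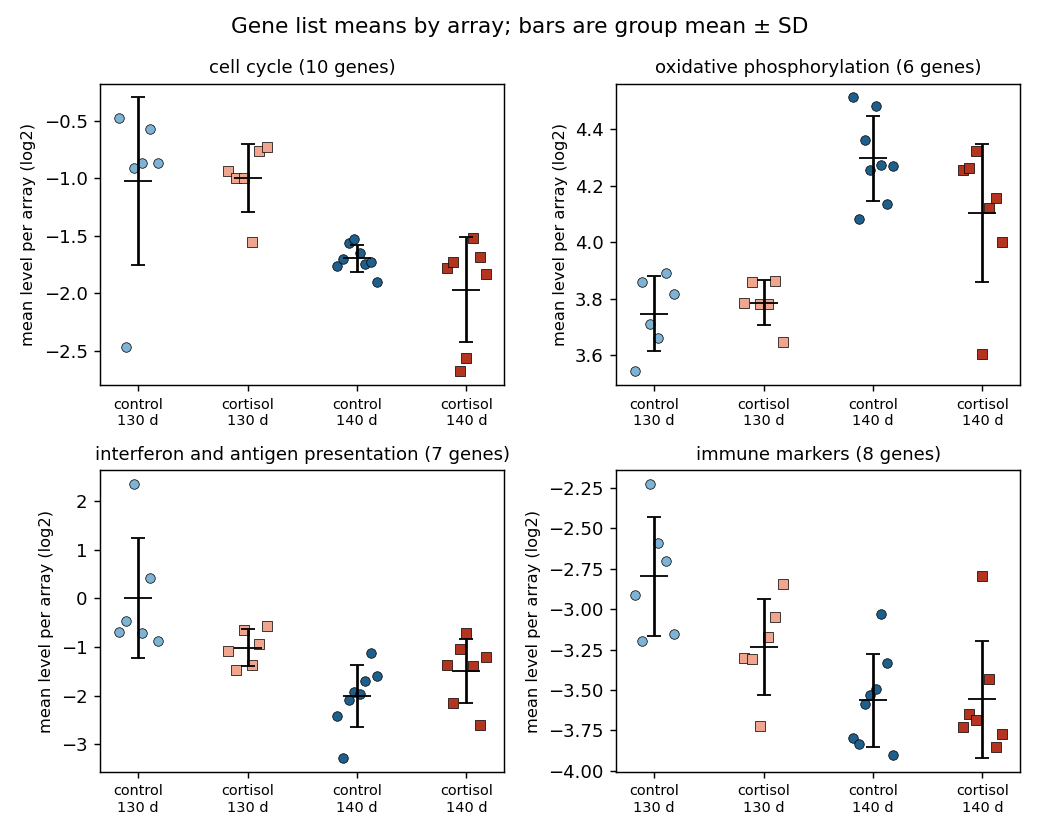
Mean level of 4 gene lists on each array, on the log2 scale after scaling to the 75th percentile, by group. Each point is 1 fetus and the bars are the group mean ± SD. Oxidative phosphorylation was higher at 140 d by 0.55 in the controls and 0.32 with cortisol, and control 130 d replicate 3 had the highest interferon mean.

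Of the lists past camera in the control age comparison, cell cycle and adipocyte markers did not pass the exact permutation test of list means. Its adjusted p was 0.0574 and 0.124. The oxidative phosphorylation, glycolysis, interferon, immune and matrix lists passed it, with adjusted p values of 0.0268 or less. The remaining lists did not pass camera in the control age comparison. Members past the threshold over all probes were 2 higher and 2 lower of 14 corticosteroid and growth factor genes, 2 higher of 5 for fatty acid oxidation, 1 higher of 7 for calcium handling, 2 higher and 1 lower of 10 for apoptosis, 3 higher of 17 ribosomal proteins, 3 higher of 5 for the proteasome, 0 of 5 endothelial and 1 lower of 5 fibroblast markers. Adjusted over the list alone, the counts were 3 and 3, 2, 1, 2 and 2, 1, 3, 0 and 2. Among the lists not tested, 1 of 3 sarcomere genes rose, 1 of 4 heat shock genes rose and 2 fell, the cardiomyocyte marker measured rose, 1 of 3 red blood cell markers fell, and 0 of the 4 glucocorticoid-responsive genes counted, 0 of 3 conduction system and 0 of 1 smooth muscle markers passed. The tricarboxylic acid cycle and nerve lists had 0 measured members.

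The count was 2635 with slide as a fixed block and 2708 as a random block, but 3, 5 and 2 in slides 2, 3 and 4 alone, each with far fewer arrays. With the slide block the list means were -0.61 for cell cycle (adjusted p = 0.051), 0.60 for oxidative phosphorylation, 0.41 for glycolysis, -0.26 for extracellular matrix, -2.30 for interferon, -0.79 for immune markers and 0.36 for adipocyte markers (adjusted p = 0.0658). Within slides 2, 3 and 4 they were -0.26, -0.65 and -0.93 for cell cycle, 0.60, 0.62 and 0.63 for oxidative phosphorylation, and 0.45, 0.41 and 0.43 for glycolysis. They were -0.44, -0.29 and 0.01 for extracellular matrix, -2.28, -2.83 and -1.74 for interferon, -0.76, -1.15 and -0.57 for immune markers, and 0.15, 0.52 and 0.64 for adipocyte markers. Control 130 d replicate 2 had a cell cycle mean of -2.47, under that of every control array at 140 d, and without it the list fell by 0.96 and TYMS by 1.95.

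**Figure D3:**
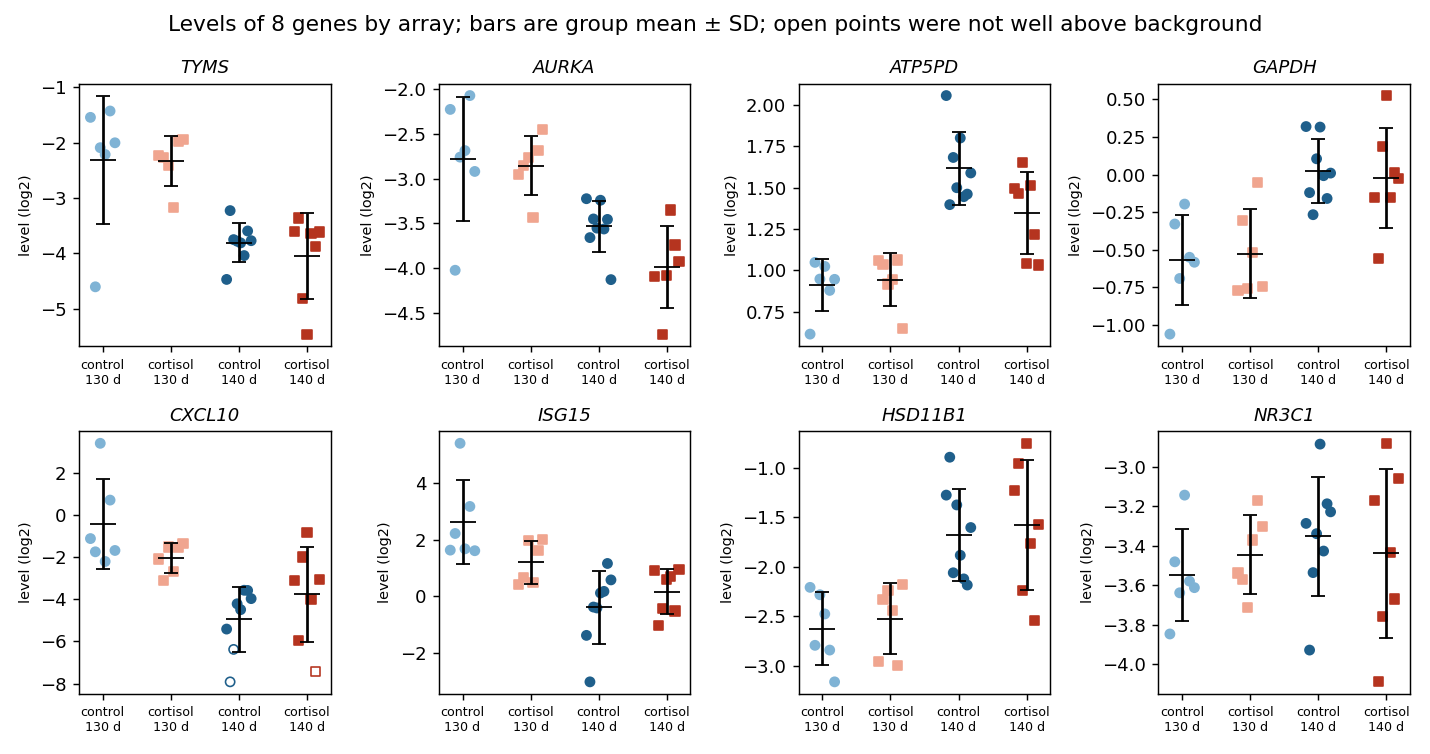
Levels of 8 genes on each array, on the log2 scale after scaling to the 75th percentile, by group. Points are fetuses, open points were not well above background, and bars are the group mean ± SD. TYMS, AURKA, CXCL10 and ISG15 were lower and ATP5PD, GAPDH and HSD11B1 higher at 140 d in the controls, whereas NR3C1 differed by 0.20.

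In the cortisol arm the same comparison of 140 d with 130 d (7 against 6 arrays) gave 1720 probes past the threshold, 631 higher and 1089 lower, and 55 named genes higher and 58 lower. The count was 339 with normexp background correction, and the share of higher probes, 36.7% here, was 63.7% with a median shift. Cell cycle genes fell again: TYMS by 1.72 ± 0.39, AURKA by 1.14 ± 0.25, and ASPM, a protein of the mitotic spindle, by 2.76 ± 0.67 (SE, adjusted p = 0.00454, 0.00445 and 0.0081). Of the 10 measured members 7 fell and 1 rose, over all probes and adjusted over the list alone alike, with a mean of -0.97 (camera adjusted p = 0.00327; adjusted p = 0.47 with an estimated correlation). ASPM was well above background on 4 of 7 arrays at 140 d, so its fall is not an exact fold, and it was -0.94 with normexp (adjusted p = 0.178). With normexp 6 of the 7 named genes here did not pass, AURKA (-0.57) and TYMS (-1.07) included. The cell cycle member that rose was CCND3, a cyclin of the G1 phase (0.78, adjusted p = 0.00616). Of 6 genes of oxidative phosphorylation 3 rose, ATP5MC1 by 0.73 ± 0.15, NDUFA12 by 0.49 ± 0.16 and ATP5PD by 0.40 ± 0.12 (SE), and 4 rose adjusted over the list alone. That mean was 0.32 (camera adjusted p = 0.04; adjusted p = 0.47 with an estimated correlation). In the exact permutation test of list means cell cycle passed (adjusted p = 0.0176) and oxidative phosphorylation did not (adjusted p = 0.0634). With 1 array left out, NDUFA12 lost its call in 9 of 13 fits, ATP5PD in 2 of 13 and the list in 8 of 13. Of the other probes of ATP5MC1, 1 of 3 had the same direction, and with the mean of its probes it was 0.10 and did not pass (adjusted p = 0.77). HSD11B1 rose by 0.94 ± 0.26 (SE, adjusted p = 0.0167), while NR3C1 (0.01 ± 0.17) and HSD11B2 (1.11 ± 0.58) did not pass. Under the alternatives HSD11B2 lay between 0.17 and 1.55 and passed in 1 (adjusted p = 0.0287 with limma).

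Of the probes higher at 140 d, 442 were called in both arms against 61.6 for independent lists, and of those lower, 606 against 102. The 2 comparisons are not independent, since they share the estimate of spread of each probe. Both set the older cohort against the younger, so the overlap does not separate age from cohort. Probes called in opposite directions numbered 2. Among members of the other lists in the cortisol arm, 1 rose and 1 fell of 14 corticosteroid and growth factor genes, 2 of 5 rose for fatty acid oxidation, 2 of 10 for glycolysis, 2 of 5 for the proteasome and 2 of 8 adipocyte markers. Of 7 interferon genes 0 passed, as did 0 of 8 immune markers, 0 of 16 matrix genes, 0 of 17 ribosomal proteins and 0 of 5 fibroblast markers. For apoptosis 3 of 10 rose, for calcium handling 1 rose and 1 fell of 7, and 1 of 5 endothelial markers rose. Adjusted over the list alone the counts differed for apoptosis (3 rose, 1 fell), calcium handling (1 rose, 2 fell), endothelial markers (1 rose, 2 fell), the proteasome (3 rose) and adipocyte markers (3 rose). Of the 4 glucocorticoid-responsive genes counted 2 rose, NFKBIA, the inhibitor of NF-kappa-B (1.30, adjusted p = 0.0049), and the transcription factor CEBPB (1.09, adjusted p = 0.0189). NFKBIA was 1.90 higher on cortisol 140 d replicate 4 than the mean of the other 6 arrays of its group, and above every other array. Of 4 heat shock genes 1 rose and 3 fell, and 1 of 3 sarcomere genes rose. Of 3 red blood cell markers 0 passed over all probes and 2 adjusted over the list alone. With slide as a block the count was 1899 fixed and 1972 random, and it was 1, 0 and 94 in slides 2, 3 and 4 alone. The cell cycle mean was -0.96 with the block and -1.27, -0.77 and -0.94 within the slides. The mean of oxidative phosphorylation was 0.32 with the block (adjusted p = 0.0784) and 0.47, 0.08 and 0.40 within them.

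Cortisol against vehicle at 130 d (6 against 6 arrays) changed no probe past the threshold. Limma called 0 of 12778 probes, with a smallest adjusted p of 0.598, and 455 had an unadjusted p under 0.05 against 639 by chance. The named genes with the smallest p on the higher side were PRP2, a prolactin-related protein (1.41 ± 0.33), the chloride channel CLCN2 (0.74 ± 0.18), MLN (0.92 ± 0.26), EP4C (0.65 ± 0.17), the luteinizing hormone receptor LHCGR (0.70 ± 0.21) and IFNG, interferon gamma (0.43 ± 0.13). PRP2 was well above background on 5 of 6 cortisol and 2 of 6 control arrays, and the other probe of MLN had the opposite sign. On the lower side they were the RNA sensor TLR7 (-0.68 ± 0.20), the interferon-induced transcription factor IRF1 (-1.26 ± 0.40), the adhesion molecule ICAM1 (-0.97 ± 0.35), the corticotropin-releasing hormone receptor CRHR1 (-0.57 ± 0.21), the cytokine IL10 (-0.79 ± 0.29) and the receptor transporter RTP4 (-1.01 ± 0.40), all with their SE and adjusted p values of 0.598 or more. TLR7, CRHR1 and IL10 had the opposite sign after normexp background correction. ICAM1 was as weak as -0.145 and IRF1 as weak as -0.58 under the alternatives. NR3C1 (0.11 ± 0.18), HSD11B1 (0.10 ± 0.27) and HSD11B2 (-0.46 ± 0.60) did not pass. The alternatives gave 0.05 to 0.45 for NR3C1 and -0.60 to 0.48 for HSD11B2.

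At 130 d, 2 lists passed camera, both lower with cortisol. The 7 interferon genes had a mean of -1.02, all 7 negative (camera adjusted p = 7.26e-06; adjusted p = 0.201 with an estimated correlation). None passed over all probes (0 of 7) and 1 adjusted over the list alone. Its members with the smallest p were IRF1, ISG15 (-1.42 ± 0.62) and the antiviral GTPase MX2 (-0.94 ± 0.39, SE). The 8 immune markers had a mean of -0.44, all 8 negative and 0 past (camera adjusted p = 0.00499; adjusted p = 0.201 with an estimated correlation), with ITGB2 at -0.61 ± 0.25, FCER1G at -0.67 ± 0.34 and LYZ at -0.72 ± 0.44 (SE). Without control 130 d replicate 3 the interferon mean was -0.55 (camera adjusted p = 0.0449) and that of the immune markers -0.32 (camera adjusted p = 0.109), which no longer passed. The exact permutation p of the interferon list mean was 0.0346 with that array (adjusted p = 0.341 over the 15 lists) and 0.0649 without it. For the immune markers the exact permutation p was 0.0455 with that array (adjusted p = 0.341). Without that array ISG15 was -0.87, MX2 -0.42, FCER1G -0.42 and LYZ -0.42. With normexp background correction the immune mean was 0.09 (camera adjusted p = 0.645). Interferon means were -1.02 with slide as a block and -0.70, -1.83 and -0.52 in slides 2, 3 and 4, and immune means were -0.44 with the block and -0.25, -1.04 and -0.02. None of the members of the other 13 tested lists passed over all probes or adjusted over the list alone, nor did any counted member of the lists not tested (0 of 4 glucocorticoid-responsive genes, for example).

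Cortisol against vehicle at 140 d (7 against 8 arrays) also gave 0 of 12778 probes with limma. The smallest adjusted p was 0.488, and 727 probes had an unadjusted p under 0.05 against 639 by chance, 184 higher and 543 lower. Higher with cortisol, with the smallest p, were BGLAP, the bone protein osteocalcin (0.92 ± 0.29), ICAM1 (0.77 ± 0.31), IRF1 (0.84 ± 0.36), VDUP1, now called TXNIP, an inhibitor of thioredoxin (0.61 ± 0.25), FLAP, a protein of leukotriene synthesis (0.56 ± 0.24), and TRAF3, a signalling adaptor (0.36 ± 0.14). Lower were the clock gene PER3 (-0.59 ± 0.16), TSPO, a protein of the outer mitochondrial membrane (-0.37 ± 0.11), PLGF, placental growth factor (-0.46 ± 0.15), LHCGR (-0.54 ± 0.19), the T cell receptor chain CD247 (-0.55 ± 0.19) and the mitochondrial glycine carrier SLC25A38 (-0.26 ± 0.09). Each is given with its SE, and each had an adjusted p of 0.808. TXNIP belongs to the glucocorticoid-responsive list, but under its older symbol it was not among the 4 members counted. With it that list would have reached the minimum of 5 genes, and the list was not tested. Without cortisol 140 d replicate 4 ICAM1 was 0.50 and FLAP 0.37, and with normexp PER3 was -0.07, PLGF -0.02, CD247 -0.10, SLC25A38 -0.00391 and BGLAP 0.32. NR3C1 (-0.09 ± 0.16), HSD11B1 (0.10 ± 0.24) and HSD11B2 (-0.79 ± 0.54, or -0.21 without control 140 d replicate 3) did not pass either.

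At 140 d, 4 lists passed camera, with 0 of their members past over all probes or adjusted over the list alone. None of the 4 passed the exact permutation test of list means. Its adjusted p was 0.602 for matrix genes and 0.438 for oxidative phosphorylation, ribosomal proteins and interferon genes. The 6 genes of oxidative phosphorylation were all negative with a mean of -0.19 (camera adjusted p = 0.0265; adjusted p = 0.541 with an estimated correlation), among them ATP5PD (-0.27 ± 0.11), ATP5MC2 (-0.13 ± 0.09) and COX5A (-0.24 ± 0.17). Of 16 matrix genes 15 were positive, with a mean of 0.20 (camera adjusted p = 0.00529; adjusted p = 0.541 with an estimated correlation), such as the protease MMP2 (0.37 ± 0.18), TGFB2 (0.45 ± 0.24) and the proteoglycan BGN (0.28 ± 0.21). Of 17 ribosomal proteins 15 were negative, with a mean of -0.08 (camera adjusted p = 0.0405; adjusted p = 0.621 with an estimated correlation), including RPL13A (-0.21 ± 0.09) and RPS2 (-0.14 ± 0.08). The 7 interferon genes were all positive with a mean of 0.52 (camera adjusted p = 0.0261; adjusted p = 0.541 with an estimated correlation), among them IRF1, the immunoproteasome subunit PSMB8 (0.53 ± 0.35) and CXCL10 (1.18 ± 0.87). The immune markers, which passed at 130 d, had a mean of 0.01. The matrix mean was 0.05 without cortisol 140 d replicate 4, and that of oxidative phosphorylation -0.11, and neither passed then. Without that array BGN was 0.12, MMP2 0.23, CXCL10 0.69, PSMB8 0.34 and ATP5MC2 -0.08, and COX5A was -0.14 without cortisol 140 d replicate 7. The ribosomal mean was -0.04 without cortisol 140 d replicate 2 and the interferon mean 0.34 without control 140 d replicate 2. Over the 15 fits with 1 array left out the call was lost in 8 for ribosomal proteins, 4 for interferon genes, 4 for oxidative phosphorylation and 1 for matrix genes.

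With slide as a block the 140 d means were -0.24 for oxidative phosphorylation, 0.12 for matrix genes, -0.10 for ribosomal proteins and 0.64 for interferon genes. Within slides 2, 3, 4 and 5 they were -0.00301, -0.45, -0.33 and -0.22 for oxidative phosphorylation, and -0.01, 0.50, -0.17 and -0.00232 for matrix genes. They were -0.18, -0.08, -0.05 and -0.06 for ribosomal proteins, and 1.26, 0.96, -0.63 and 0.26 for interferon genes, so the matrix and interferon means changed sign between slides. At 140 d slide 4 held 1 control and 1 cortisol array, and slide 5 held 3 control arrays and 1 cortisol array. The values of those slides therefore rest on single fetuses. In 68 of 100 splits of the 130 d arrays and 14 of 100 of the 140 d arrays, as many lists passed camera as in the real groups.

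The difference of the cortisol effect between 140 d and 130 d asks whether the longer infusion in older fetuses had another effect than the shorter infusion in younger ones. Limma called 0 of 12778 probes (smallest adjusted p = 0.203), with 743 at an unadjusted p under 0.05 against 639 by chance. IRF1 (2.11 ± 0.53), ICAM1 (1.73 ± 0.47) and FLAP (1.25 ± 0.36) were the named genes with the smallest p on the positive side, and LHCGR (-1.25 ± 0.28), PER3 (-1.02 ± 0.24) and MLN (-1.45 ± 0.35) on the negative side, with SE and adjusted p values between 0.204 and 0.337. Among the alternatives the weakest values were 0.61 for ICAM1, 1.21 for IRF1 and -0.66 for MLN, with the sign kept. NR3C1 (-0.19 ± 0.24), HSD11B1 (-0.01 ± 0.36) and HSD11B2 (-0.33 ± 0.81, or 0.24 without control 140 d replicate 3) did not pass. The interferon list was the 1 list past camera, with a mean difference of 1.53 and all 7 genes positive (camera adjusted p = 4.66e-06; adjusted p = 0.346 with an estimated correlation). Of its genes 0 passed over all probes and 1 adjusted over the list alone, with ISG15 at 1.98 ± 0.83 and CXCL10 at 2.78 ± 1.30 (SE). No member of the other 14 tested lists passed over all probes (0 genes). Adjusted over the list alone, 2 immune markers were positive and 1 corticosteroid or growth factor gene, 1 calcium handling gene and 1 adipocyte marker negative. The interferon mean difference was 1.66 with slide as a block, and 1.96, 2.79 and -0.12 in slides 2, 3 and 4. Slide 4 held only 1 array of each arm at 140 d. Across the 12695 probes without missing values the cortisol changes at the 2 ages had a Pearson correlation of -0.164, within the -0.231 to 0.237 that 100 draws of unchanged groups gave, and probes are not independent replicates.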

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

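The tests of fewer white blood cells and of a cohort difference for the interferon list, and those of white blood cells of every kind and of myeloid cells on 1 array, were chosen only after the results were seen. Of 296 groups of values, 35 had an array far from the others of its group, against 14.8 expected by chance at 1 in 20. The distances below are on the log2 scale from the mean of the group's other arrays.

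Cortisol 140 d replicate 4 stood far from its group for 9 of these values. It was higher for FCER1G (1.96), ICAM1 (1.84), IL10 (1.74) and FLAP (1.34) and for the mean of the immune markers (0.894), and lower for TUBA4A (-2.55), NDUFA12 (-1.24) and ATP5MC1 (-0.87). Its mean rank correlation with the other arrays differed by -0.0184. In all, 294 probes were more than 4-fold higher and 48 more than 4-fold lower than the mean of its group, 342 together, against at most 171 on any other array. Among the named genes were the early-response gene FOS (5.11), the prostaglandin enzyme PTGS2 (4.23), the complement component C3 (4.19), the granule protein LTF (4.49) and the neutrophil chemokine CXCL8 (3.45), chosen after their values were seen. Its 75th percentile of intensity, 602, was the lowest of all arrays, with 78.7% of its spots well above background against 77.0% to 87.0% on the others. The other arrays of its slide had a median deviation of 0.073 on the same probes, which argues against the slide. Of the 8 immune markers 4 were higher than on every other array of the group (CD14, LYZ, ITGB2 and FCER1G). The T cell genes CD3D (-0.09) and CD3E (0.27) were not among them. All 4 were among the 5 markers counted as myeloid, though ITGB2 is an integrin of leukocytes in general. The limits for both counts were set after the values were seen, so they cannot decide between myeloid cells and white blood cells of every kind. An inflamed tissue piece with more white blood cells may explain part of the pattern, and an effect of handling on early-response genes stays untested.

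Control 140 d replicate 1 stood far from its group for 8 values. These were UGT1A9 (2.09), TGFB1 (-1.63), TRAF3 (-0.89), MMP2 (-0.77), TSPO (0.58), PLIN1 (0.52), RPL13A (0.50) and its mean rank correlation with the other arrays (-0.0112). Control 130 d replicate 2 stood apart for 6 values, with ASPM (-4.53), TYMS (-2.75), INHBA (-1.69) and the cell cycle mean (-1.73) lower and LPL (1.00) and SLC25A33 (0.82) higher, each in the direction of the age change of the controls. Control 130 d replicate 3 stood apart for MX2 (3.09), MX1 (2.77) and FCER1G (1.47). The others were ICAM1 in control 140 d replicate 5 (-0.80), COL3A1 in control 140 d replicate 2 (-0.65), HSD11B2 in control 140 d replicate 3 (4.60), PRP2 in cortisol 130 d replicate 1 (-1.04), CDK4 (-0.20) and LEP (0.42) in cortisol 130 d replicate 2, the cell cycle mean in cortisol 130 d replicate 4 (-0.67), and ATP5PD in cortisol 130 d replicate 6 (-0.36).

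The effect of cortisol on the interferon list differed between the ages by 1.53 on the log2 scale, past camera at its preset correlation (adjusted p = 0.346 with an estimated correlation, 0.274 with fry). The matching pattern in the controls was the fall of the interferon list by 2.02 between 130 d and 140 d. The list fell by 1.25 more than the immune markers did (difference -1.25, exact permutation p = 0.00366, 2-sided, not corrected for its choice among 15 lists). Only 3 of the 8 markers passed, and they need not stand for every kind of white blood cell. The test therefore cannot decide whether fewer white blood cells were the cause. Of 10000 random lists of the same brightness, the central 95% lay between -0.49 and 0.31, which argues against a shift of all probes of that level. The change in the cortisol arm was -0.48, and the difference between the arms, which is the same 1.53, had a permutation p = 0.00849 (0.0144 without control 130 d replicate 3), or 0.127 multiplied by the 15 lists it was picked from. A cohort difference, alike in both arms or not, therefore stays open, as does age itself.

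Other splits of the arrays were drawn 100 times per comparison. For age in the controls 1 split, the real one, gave 2443 probes or more (highest other 5), which argues against chance for that count. For the lists 3 splits, the real one included, gave 7 or more. The highest other was 9, above the real count, and there was no correction over the comparisons. The list count is therefore much weaker evidence than the probe count. For age in the cortisol arm 1 split gave 1720 probes or more (highest other 897), but 46 gave 2 lists or more (highest other 5). For the cortisol comparisons the real count of probes was 0, which every split reaches, so that count decides nothing. For cortisol at 130 d these were 100 splits (highest other 108), while 27 gave 455 or more at an unadjusted p under 0.05 (highest other 1417), and 68 gave 2 lists or more (highest other 5). For cortisol at 140 d they were 100 splits for 0 probes (highest other 93), 60 for 727 (highest other 1688) and 14 for 4 lists (highest other 7). For the difference between the ages they were 100 for 0 probes (highest other 1), 20 for 743 (highest other 1281) and 68 for 1 list (highest other 6). By the lists and the unadjusted counts chance was not excluded for any cortisol comparison, nor for the lists of the cortisol arm's age comparison. Single splits with 108 and 93 probes, where the real groups gave 0 and the median split 0, would point to a structure among the arrays, which was not tested.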

How the results depend on the processing

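Slides 2, 3 and 4 alone and the fit without the 2 arrays that stood apart were chosen only after the data were seen. No setting gave more than 1 probe for cortisol at either age, and single left-out arrays gave 0. The count for age in the controls was 536 with normexp background correction (326 higher, 210 lower) and 3, 5 and 2 in slides 2, 3 and 4 alone, and 1649 to 2823 with each array left out in turn. In the cortisol arm it was 339 with normexp (177 higher, 162 lower), 765 with replicate and slide blocks, 2970 with array weights, 2616 at an adjusted p under 0.10, 1, 0 and 94 in slides 2, 3 and 4 alone, 2897 without the 2 arrays, and 1287 to 2419 with each array left out. The share of higher calls followed the scaling. For age in the controls it was 51.1% in the report, 70.6% with a median shift and 71.3% with the authors' table, and in the cortisol arm 36.7%, 63.7% and 64.1%, so the balance of rises and falls is not known from these data. Slide 2 alone gave 1 probe for cortisol at 140 d. The difference between the ages gave 1 probe with a replicate block, 1 with replicate and slide blocks, and 0 to 2 with each array left out. The labels do not say that numbers shared between groups pair the samples, and the values do not settle it. Of 37 pairs of the same number 13 had a correlation over 0.1 and 10 were the best match. Between the arms the median for the same number was 0.078 against -0.035 for other numbers at 130 d. At 140 d it was 0.088 against -0.021. Pairs of the same number often shared a slide, though not always, and the effects of number and slide were not separated here. Over all pairs of arrays from different groups, of the same number or not, the medians were 0.0552 on the same slide and -0.0263 across slides. With the replicate block the counts were 2494 and 1789 for age in the controls and the cortisol arm. Lists past the threshold for cortisol at 130 d were 2 in the report, 0 with an estimated correlation, 0 with fry, 4 in slide 3 and 0 in slide 4 alone, and 1 to 2 with each array left out. At 140 d they were 4 in the report, 1 with quantile normalization, 0 with replicate and slide blocks, 2 with the groups alone, 1 with array weights, 0 with an estimated correlation, 0 with fry, 2, 2 and 0 in slides 2, 3 and 4 alone, 1 without the 2 arrays, and 1 to 6 with each array left out. For age in the controls they were 7 in the report, 0 with an estimated correlation and 9 with fry, which did not include the matrix list (fry adjusted p = 0.102). In the cortisol arm they were 2 in the report, 1 with a median shift, 5 with normexp, 1 with the authors' table, 1 with the strict filter, 1 with slide fixed, 0 with replicate and slide blocks, 1 with the groups alone, 4 with array weights, 1 with the mean of probes, 0 with an estimated correlation, 5 with fry, 1 and 4 in slides 3 and 4 alone, 7 without the 2 arrays, and 1 to 6 with each array left out. For the difference they were 1 in the report, 3 with the mean of probes, 0 with an estimated correlation, 0 with fry, 4 and 0 in slides 3 and 4 alone, and 1 to 2 with each array left out. Signs that turned were those of genes that had not passed. With normexp at 130 d these were TLR7 (0.40), CRHR1 (0.42), IL10 (0.28) and HSD11B2 (0.48), at 140 d LHCGR (0.042), COX5A (0.043) and NR3C1 (0.048), and in the cortisol arm NR3C1 (-0.11). NR3C1 in the cortisol arm was -0.054 with slide fixed, -0.0397 with a replicate block, -0.061 with replicate and slide blocks, and -0.086 without the 2 arrays, and -0.086 to 0.12 with each array left out. It was -0.18 to 0.023 for cortisol at 140 d. HSD11B1 for cortisol at 140 d was -0.025 with slide fixed and -0.041 to 0.26 with each array left out, and at 130 d -0.00255 to 0.20. For the difference HSD11B1 was 0.00774 with quantile normalization, 0.00384 with a median shift, 0.0023 with a replicate block, 0.12 with replicate and slide blocks and 0.023 with the mean of probes, and -0.15 to 0.15 with each array left out, and HSD11B2 was -0.60 to 0.24. Relative to other genes, list directions turned for oxidative phosphorylation at 140 d in slide 2 (-0.00301), and in slide 4 for matrix genes (-0.17) and interferon genes (-0.63) at 140 d, matrix genes with age in the controls (0.0065) and interferon genes for the difference (-0.12). Slide 4 held only 1 array of each arm at 140 d.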

Other observations

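The gene groups below were chosen after their values were seen. Among 11 named mitochondrial carriers of the SLC25 family, 4 rose between 130 d and 140 d in the controls. The family was picked after its values were seen, so no test of the group is given. They were SLC25A33, the adenine nucleotide carriers SLC25A6 (0.93 ± 0.14, SE) and SLC25A4 (0.86 ± 0.14), and SLC25A26, a carrier of S-adenosylmethionine (0.51 ± 0.15). In the cortisol arm 3 of 11 rose, SLC25A33 by 0.90 ± 0.20, SLC25A6 by 0.85 ± 0.14 and SLC25A4 by 0.83 ± 0.14. SLC25A5, another adenine nucleotide carrier, differed by 0.05 ± 0.15 in the controls and did not pass.

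Of 27 probes described as genes of the major histocompatibility complex, which present antigens, 11 fell in the controls between 130 d and 140 d. Several of these probes measure near-identical genes or alleles and are not independent. Their median change was -1.13 in the controls and 0.21 in the cortisol arm, where 0 passed. A probe for the fetal beta subunit of hemoglobin fell by 3.17 ± 0.82 (SE, adjusted p = 0.00907) in the controls and changed by -4.72 ± 0.84 (SE, adjusted p = 0.00089) with cortisol. It was well above background on 6 of 6 control arrays at 130 d and 7 of 8 at 140 d, and on 6 of 6 and 5 of 7 with cortisol. These falls are therefore not exact folds. A probe described as beta hemoglobin, HBB, fell by 2.00 ± 0.58 (SE, adjusted p = 0.0176) in the controls, while the HBB probe chosen for the gene, another one, differed by -1.54 (adjusted p = 0.0861) and did not pass.

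The cortisol change at 130 d and the age change of the controls use the same 6 control arrays. Across 12695 probes, which are not independent replicates, they had a correlation of 0.313, against 0.538 in unchanged groups that share controls (95% of 100 draws between 0.283 and 0.707). Their covariance was 0.0338 against 0.0299 in unchanged groups, a difference of 0.00393. That covariance lay inside the 0.0145 to 0.0552 of unchanged groups that share controls. With the controls parted over all 20 ways into 3 and 3, the mean covariance was 0.00616, and single ways gave -0.032 to 0.0343. Unchanged groups gave -0.0278 to 0.026, but each draw was parted in 1 way only. Such a range is too wide for a mean over 20 ways, so the parted controls decide nothing. By the covariance with shared controls, the shared arrays may account for the relation, and an effect of cortisol along the course of age was not shown by it.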
